A study of Homo sapiens with 18 samples.

How the data were processed

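Nascent RNA was measured in HEK293 cells, an established human embryonic kidney line, after electroporation of antisense morpholino oligonucleotides (MO), which are synthetic oligomers that pair with an RNA and block its use. The 4 morpholinos were directed against U12, U4atac and U6atac, which are snRNAs of the minor spliceosome, and against U2, an snRNA of the major spliceosome. A control morpholino served as the reference. Per the labels' protocols, the uridine analogue EU was given 6 h after electroporation and cells were collected 2 h later. EU-bearing RNA was captured by Click-iT chemistry, and stranded libraries were made from 5 ng of it after removal of ribosomal RNA. The 18 libraries comprised 6 with the control morpholino and 3 with each of the 4 others. Grouping followed the sample titles. Nothing in the labels said whether the replicates of a group were separate cultures, so every p-value measures the spread between these samples, which may be technical.

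The submitters' processing notes name HISAT2, with no version, and the build hg38. The quantifier, its annotation and its strand setting are not given in the sources used here. Each deposited table listed 44787 gene symbols with a single value each. The values summed to 1000000 in every library and were therefore taken as TPM, a unit of transcripts with a fixed total per library, as deposited by the authors. TPM keeps no record of depth, so the depth per library is unknown and no counting interval was computed. Because the values of a library share a fixed total, a rise of abundant RNAs lowers every other value in that library. Gene totals hold no information on introns or splice sites, so splicing itself was not measured here. Genes with near-identical copies (7SL and snRNA pseudogenes, ribosomal protein genes, CBS and CBSL) are uncertain, because reads may have been divided between copies.

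Values were analysed as log2(TPM + 1), which understates the change of low genes. Genes with at least 1 TPM in at least 3 of the 18 libraries were tested, which left 17460 genes. limma 3.58.1 in R 4.3.3 was fitted with a mean per group over the 5 groups, with trend and robust settings (13 residual and a median of 5.90 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The comparisons were each morpholino with the control, U2 MO with the mean of the other 3 morpholinos, and the 3 pairs among U12, U4atac and U6atac MO. Values are given as mean ± SD over n libraries, and log2 fold changes with their standard error (SE). Target snRNAs were compared by a two-sided exact permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots.

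Gene lists (23) were fixed before the data were examined, as were the comparisons, the test, the naming rule, the split of the control libraries by number and all alternatives except those named as added. The lists were recalled U12-type intron genes, minor spliceosome proteins, U2 snRNP proteins, other snRNP proteins, snRNA and other non-coding RNAs, SR proteins, hnRNP proteins, immediate early genes, p53 targets and integrated stress response genes. The others were heat shock, interferon response, DNA replication, mitosis, snoRNA host, mitochondrially encoded, nuclear oxidative phosphorylation, cholesterol synthesis, replication-dependent histone and ribosomal protein genes, with mesenchymal, haematopoietic and keratin markers of other cell types. The U12-type list was recalled from general knowledge, since a genome sequence was not used here. Lists were tested with camera (preset correlation of 0.01), with camera using an estimated correlation, and with fry, over 21 lists. Mesenchymal and keratin markers had 3 tested members each and were given values only. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

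Genes were named by rule. For each comparison with the control, these were up to 10 of the largest rises and falls past the threshold with at least 5 TPM in either group and no overlap between the groups' values, and up to 4 members of each list past the threshold. Where a list had no such member, its 2 members of highest mean could be named. The 4 target snRNAs were named, and the 5 largest changes in each direction for U2 MO against the other morpholinos. List members named for that comparison beyond these, for U12 MO against U4atac MO, and for the 2 sets of controls were chosen after their values were seen, as was HERPUD1. Coordinates come from GENCODE 29 on hg38, matched by symbol (29860 symbols), and are not those of the submitters' annotation. Length and GC content were available for 82.1% of the genes tested.

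Alternatives covered the pseudocount, the filter, the scaling between libraries, the limma settings, the groups in the fit, controls 1 to 3 or 4 to 6 alone, the replicate number as a block, and each library left out in turn. Added after seeing the data were sample quality weights, rescaling over protein-coding genes, the omission of 3 libraries together, and a split of the controls into odd and even numbers. The fit was tested on simulated data, with 200 of 17460 genes changed in each of 5 draws. For U4atac MO against the control, it recovered 0.629%, 21.0% and 74.7% of genes changed by log2 folds of 0.5, 1 and 2, with 3 false calls per draw. The corresponding shares were 0.829%, 19.5% and 74.8% for U12 MO, 1.45%, 22.0% and 78.0% for U6atac MO, and 0.617%, 18.6% and 72.5% for U2 MO. Simulated values were independent between genes and libraries and held no sets of controls, so the false calls do not give the error rate in the real data. No input column was left unused, and no pair of libraries held identical values.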

Results

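Newly made RNA was measured in 18 libraries of HEK293 cells, 6 with a control morpholino and 3 each with morpholinos against U12, U4atac, U6atac or U2 snRNA. The expression values were TPM as deposited by the authors, whose depth is unknown. Genes listed above 0 numbered 13930 in U2 MO 1 and 19119 to 22726 in the other libraries. Short non-coding RNAs took 20.1% to 44.1% of the values, with the highest share in U4atac MO 3, and protein-coding genes took 45.4% to 70.5%. Mitochondrially encoded RNAs took 2.31% to 8.42%.

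The 6 control libraries formed 2 sets by their numbers. HSPA1A, a stress-inducible HSP70 chaperone, was at 96.7 ± 13.6 TPM (SD, n = 3) in controls 1 to 3 and 12.9 ± 3.74 TPM (SD, n = 3) in controls 4 to 6. HSPA5, the chaperone BiP of the endoplasmic reticulum, was at 1164 ± 558 and 196 ± 19.3 TPM. The replication-dependent histone gene HIST1H2AB was at 98.8 ± 14.3 and 591 ± 86.6 TPM. With limma, 733 genes differed between the sets, 177 higher and 556 lower in controls 1 to 3. They included 37 of the 58 histone genes tested, all lower in controls 1 to 3, where the list had a median log2 difference of -1.49. Heat shock genes had a median of 0.69, ribosomal protein genes -0.51, nuclear oxidative phosphorylation genes -0.62 and mitochondrially encoded genes -1.16. The camera adjusted p was 3.95e-07 or less for ribosomal protein and histone genes. Other lists that passed included U12-type genes (median -0.30, camera adjusted p = 0.0469), immediate early genes (0.58, 2.86e-06) and integrated stress response genes (0.35, 2.34e-04). Camera calls with the preset correlation thus arose between libraries with the same morpholino. With an estimated correlation the adjusted p was 0.231 or more for every list. Single libraries departed from the sets. Relative to the mean of 18 libraries, mitochondrially encoded genes had a median of -0.22 in Control MO 2, within the -0.22 to 0.10 of controls 4 to 6. In Control MO 1 and 3 it was -1.67 and -1.68. Ribosomal protein genes were at 0.54 in Control MO 4 but -0.13 and -0.14 in Control MO 5 and 6, against -0.59 to -0.24 in controls 1 to 3. U12 MO libraries stood near controls 1 to 3, with HSPA1A at 90.4 ± 19.8 and HIST1H2AB at 77.9 ± 13.2 TPM (SD, n = 3). Mitochondrially encoded genes went the other way. Relative to the mean of 18 libraries, their median averaged 0.09 in U12 MO, -1.19 in controls 1 to 3 and -0.07 in controls 4 to 6. In U2 MO, HSPA1A was at 8.07 ± 5.39 and HIST1H2AB at 570 ± 66.4 TPM (SD, n = 3). U4atac and U6atac MO were less clear. HSPA1A was at 15.2 ± 6.76 and 21.9 ± 5.79 TPM there, and HIST1H2AB, between the sets, at 421 ± 244 and 289 ± 180 TPM. The histone gene HIST1H3F was at 7.16 and 3.89 TPM there, near controls 1 to 3 (4.39 TPM) and far from controls 4 to 6 (73.1 TPM). U4atac MO 3 had a mean Pearson's r of 0.924 with controls 1 to 3 and 0.927 with controls 4 to 6. Over all genes, 3 of 3 U12 MO libraries and 0 of the other 9 morpholino libraries were closer to controls 1 to 3. The tests against all 6 controls were therefore repeated against each set.

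The targeted snRNAs were read first. RNU12, at chromosome 22 from 42615244 to 42615393 on the plus strand and overlapping Z93241.1, was between 5.22 and 26.3 TPM in controls (SD 9.43, n = 6) and at 6.33 ± 2.06 TPM (SD, n = 3) in U12 MO. The ratio of the means was 0.396 (two-sided exact permutation p = 0.119, smallest possible 0.0119). RNU6ATAC, at chromosome 9 from 134164439 to 134164564 on the minus strand, was at 2100 ± 537 TPM (SD, n = 6) in controls and 1716 ± 564 TPM (SD, n = 3) in U6atac MO (exact permutation p = 0.381), and is listed at 0 in U2 MO 1. RNU4ATAC, at chromosome 2 from 121530881 to 121531007 on the plus strand and opposite to CLASP1, and RNU2-1, at chromosome 17 from 43233787 to 43233977 on the minus strand within CCDC200, are listed at 0 in all 18 libraries. A morpholino blocks an snRNA and need not lower it, so these levels do not check its action.

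The comparison of U12 MO with the control asked which nascent transcripts depend on the snRNA that recognises the branch point of U12-type introns. Genes recalled as carrying such introns had a median log2 fold change of -0.12, with 40 of 61 members below 0. The standard error of the mean over genes was 0.031, which takes genes of the same libraries as independent replicates and so understates the uncertainty. UBL5 was at 151 ± 48.2 TPM (SD, n = 3) against 195 ± 88.9 TPM (SD, n = 6), and NOP2, a nucleolar methyltransferase, at 135 ± 28.9 against 172 ± 29.2 TPM, neither past the threshold. Replication-dependent histone genes had a median of -0.79 with 56 of 58 members below 0, and HIST1H3B was at 1110 ± 54.1 against 2413 ± 1291 TPM. Mitochondrially encoded genes had a median of 0.75 with 15 of 15 members above 0. HERPUD1, which acts in endoplasmic reticulum protein degradation, was at 288 ± 65.6 against 121 ± 32.0 TPM (log2 fold change 1.27 ± 0.24, limma adjusted p = 0.481).

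limma called 0 of 17460 genes for U12 MO against all controls, with 995 at an unadjusted p under 0.05 (756 higher, 239 lower) where 873 are expected by chance. With sample quality weights 942 genes passed (774 higher, 168 lower), and with no filter 3. By camera, the U12-type (adjusted p = 1.21e-04), histone (1.26e-25) and nuclear oxidative phosphorylation lists (median -0.26, adjusted p = 3.32e-06) were lower than other genes. Ribosomal protein (median -0.05, adjusted p = 3.31e-04) and snoRNA host genes (median -0.16, adjusted p = 0.00908) were also lower. The mitochondrial (4.32e-07), immediate early (median 0.50, 3.67e-06), heat shock (0.37, 0.00226), integrated stress response (0.22, 0.00106), hnRNP (0.21, 0.00226), mitosis (0.23, 0.00908) and cholesterol synthesis lists (0.24, 0.03) were higher. With an estimated correlation, the adjusted p was 0.392 or more for every list. Adjusted over the list alone, 3 mitochondrial genes and 1 gene each of 5 other lists passed, all higher. The histone call held in all 32 alternatives. That of the cholesterol list ended in 12, including either scaling and the omission of Control MO 1, Control MO 3, U12 MO 1 or U12 MO 2 (median 0.13 without U12 MO 2 and 0.14 without U12 MO 3). Without U12 MO 3 the median was 0.07 for heat shock, 0.11 for hnRNP and 0.14 for mitosis genes, all no longer past the threshold, and 0.22 for immediate early genes. Those of nuclear oxidative phosphorylation and ribosomal protein genes turned to 0.01 and 0.08. Without U12 MO 1 it was -0.03 for U12-type and -0.07 for snoRNA host genes, the latter no longer past the threshold, and -0.20 for ribosomal protein genes. Without Control MO 1 it was 0.47 for mitochondrial genes. Mitosis genes had a median of 0.15 without U12 MO 2. Without Control MO 4 it was -0.13 for nuclear oxidative phosphorylation genes and turned to 0.08 for ribosomal protein genes, and without Control MO 5 it was -0.09 for snoRNA host genes. That of ribosomal protein genes was also -0.15, -0.16, -0.03 and -0.17 without Control MO 1, Control MO 3, Control MO 6 or U12 MO 2. Against controls 1 to 3, where 2 genes were called (RNA5SP370 and RNU1-2, both lower), the medians were 0.04 for U12-type (0.15 over all genes, camera adjusted p = 0.048), -0.04 for histone, 1.27 for mitochondrial, 0.12 for heat shock, 0.16 for ribosomal protein and 0.11 for nuclear oxidative phosphorylation genes. Against controls 4 to 6, with 377 genes called (189 higher, 188 lower), they were -0.28, -1.60, 0.12, 0.46, -0.36 and -0.55. The calls that ended against controls 1 to 3 were those of the immediate early (median 0.23), hnRNP (0.16), stress response (0.18), snoRNA host (0.10), heat shock, nuclear oxidative phosphorylation and ribosomal protein lists. Those that ended against controls 4 to 6 were of the mitosis (0.08), cholesterol (0.11) and mitochondrial lists.

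The comparison of U4atac MO with the control asked the same of the snRNA that chaperones U6atac into the minor spliceosome. RPS13, a protein of the small ribosomal subunit (chromosome 11 from 17074389 to 17077787), fell from 1160 ± 201 TPM (SD, n = 6) to 565 ± 45.8 TPM (SD, n = 3), a log2 fold change of -1.02 ± 0.18 (limma adjusted p = 0.0185). HNRNPK, an RNA-binding protein (chromosome 9 from 83968083 to 83980616), fell from 368 ± 50.3 to 200 ± 28.0 TPM (log2 fold change -0.88 ± 0.17, adjusted p = 0.0286). MAPK9, the kinase JNK2 and a member of the U12-type list (chromosome 5 from 180233143 to 180292099), fell from 37.0 ± 5.55 to 19.8 ± 2.30 TPM (log2 fold change -0.86 ± 0.17, adjusted p = 0.0331). NUCB2, which encodes the precursor of nesfatin (chromosome 11 from 17208153 to 17349980), fell from 15.5 ± 3.95 to 4.98 ± 2.14 TPM (SE of the log2 fold change 0.27, adjusted p = 0.0185). EVA1A, a regulator of autophagy (chromosome 2 from 75469302 to 75569722), rose from 1.16 ± 1.57 to 7.34 ± 1.19 TPM (log2 fold change 2.19 ± 0.47, adjusted p = 0.038).

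In all, 21 genes rose and 87 fell with U4atac MO, at a median absolute log2 fold change of 1.09, and 2702 had an unadjusted p under 0.05. Of the 87 falls, 54 lay below all 15 other libraries, and 10 of the 21 rises lay above them. The rest overlapped with controls or other morpholinos. Among the falls were ASNS, the asparagine synthetase of the amino acid response (98.2 to 55.9 TPM), and the cell cycle genes CDC25A (253 to 137 TPM) and CCNA2 (60.4 to 30.8 TPM). PRIM1, the catalytic primase subunit, fell from 17.3 to 5.21 TPM and HSPA4L, an HSP110-type chaperone, from 10.3 to 2.61 TPM. The sterol synthesis gene CYP51A1 (41.2 to 21.5 TPM) fell, as did the respiratory chain genes UQCRB (135 to 52.4 TPM) and COX5A (610 to 398 TPM). RPL4 (5989 to 3149 TPM), RPL7 (390 to 212 TPM) and the snoRNA host SNHG5 (540 to 306 TPM) fell too. The transcriptional coactivator SUB1 (45.9 to 17.7 TPM) and TPT1-AS1 (16.6 to 3.38 TPM) were among the largest falls, with CBSL (27.2 to 4.52 TPM), RP11-315D16.2 (6.85 to 0.101 TPM) and RP11-417N10.4 (7.27 to 1.48 TPM). The 7SL pseudogene RN7SL428P went from 6.98 ± 2.74 TPM to being listed at 0, while RN7SL655P, listed at 0 in every control, reached 5.33 ± 2.47 TPM (limma adjusted p = 8.81e-04). The zinc finger genes ZNF267 (22.4 to 47.2 TPM) and HKR1 (7.61 to 17.6 TPM) rose, as did NOL4 (1.81 to 6.62 TPM), AC008982.2 (6.83 to 25.3 TPM), RP11-161M6.2 (2.96 to 11.2 TPM), XX-FW80269A6.1 (0.0341 to 7.91 TPM) and RP5-1120P11.1 (0.267 to 5.95 TPM). ZNF267 was also at 37.3 to 44.5 TPM in the U6atac MO libraries, and at 28.6 TPM in U4atac MO 3 against up to 27.3 TPM in controls.

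**Figure D1:**
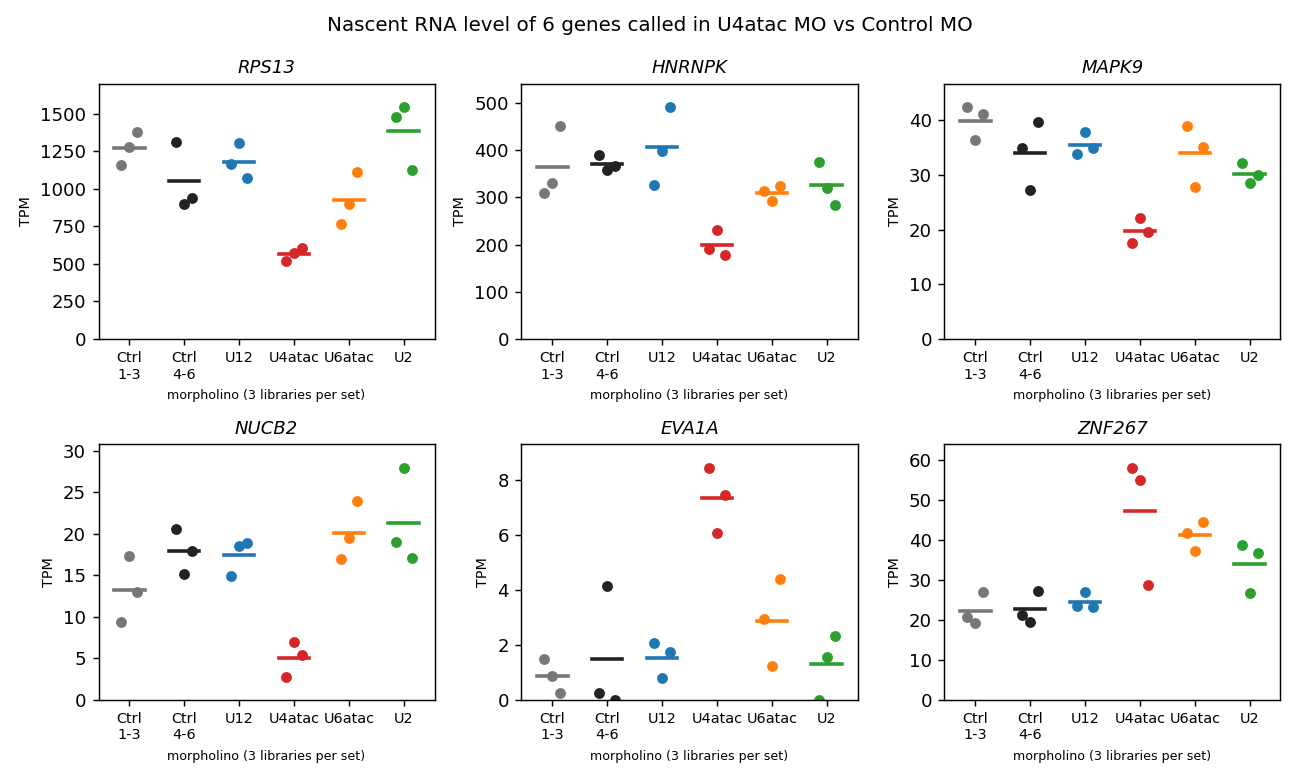
TPM of 6 genes called with U4atac MO (vertical axes) in each library, shown as points by set of 3 libraries (controls 1 to 3, controls 4 to 6 and the 4 morpholinos), with a line at the mean of each set. RPS13 falls from 1160 to 565 TPM, and EVA1A rises from 1.16 to 7.34 TPM.

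As a group, hnRNP genes had a median log2 fold change of -0.47 with U4atac MO, and 22 of 26 were below 0. A single member (HNRNPK) passed over all genes and 8 adjusted over the list alone. U12-type genes had a median of -0.25, with 41 of 61 below 0, 1 member called (MAPK9) and 2 adjusted over the list alone. The standard error of the mean over genes was 0.054, again with genes taken as independent replicates. Heat shock genes had a median of -0.45 (1 called lower, 3 adjusted over the list alone), DNA replication genes -0.27 (1 and 6) and U2 snRNP proteins -0.17 (0 and 5). SR proteins had a median of -0.29 (0 and 0), and mitochondrially encoded genes 0.88 (0 and 6 higher). Ribosomal protein genes had 3 falls over all genes and 8 adjusted over the list alone around a list median of -0.03, which turned to 0.13 with median-of-ratios scaling. camera placed the hnRNP (adjusted p = 2.95e-05), U12-type (0.00577), heat shock (0.00568), DNA replication (0.00209), U2 snRNP (0.0264) and SR lists (0.0221) lower and the mitochondrial (4.78e-07) and histone lists (median 0.18, 0.0471) higher. With an estimated correlation the adjusted p was 0.544 or more for every list, and the unadjusted p for hnRNP genes was 0.0366. In fry, which does not compare a list with other genes, hnRNP genes moved down with an adjusted p of 0.0316. Against controls 1 to 3 and 4 to 6 in turn, the medians were -0.52 and -0.39 for hnRNP, -0.03 and -0.40 for U12-type, -0.69 and -0.39 for heat shock, -0.11 and -0.44 for DNA replication, 0.01 and -0.30 for U2 snRNP, -0.31 and -0.30 for SR, 1.44 and 0.36 for mitochondrial and 0.85 and -0.58 for histone genes. The calls of the hnRNP and mitochondrial lists held in all 32 alternatives. Against controls 1 to 3 those of the U12-type, U2 snRNP, SR and DNA replication lists ended, as did that of the heat shock list against controls 4 to 6. Median-of-ratios scaling ended those of the U2 snRNP (median -0.0052), SR (-0.13) and histone lists (0.34), and quantile normalization those of the U2 snRNP, SR, heat shock and DNA replication lists. Without U4atac MO 3 the medians were -0.06 for U12-type, -0.07 for DNA replication, -0.24 for heat shock, -0.06 for U2 snRNP and -0.14 for SR genes, the last 2 no longer past the threshold. Without U4atac MO 2 the U2 snRNP (-0.24) and heat shock calls (-0.46) ended. Without U4atac MO 1 the medians were -0.32 for U2 snRNP and -0.44 for DNA replication genes. The histone call ended without Control MO 1, 2 or 3 (0.08, 0.05 and -0.0047), U4atac MO 1 or 2 (-0.11 and 0.09) or U2 MO 1. Its median was 0.31, 0.37, 0.38 and 0.59 without Control MO 4, 5 or 6 or U4atac MO 3.

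All 108 genes called with U4atac MO kept their sign against each control set. This is no independent check, since they were called against the same 6 controls. Against controls 1 to 3, 706 genes (265 higher, 441 lower) passed, but against controls 4 to 6 only 7 (1 higher, 6 lower). Of the 108, 5 were called in both (RN7SL655P, IP6K1, MCMBP, NUCB2 and PDHB). With median-of-ratios scaling, which moved the median of all genes from -0.03 to 0.10, 41 genes rose and 28 fell (quantile normalization, 26 and 59), and without U4atac MO 3, 57 rose and 21 fell. HNRNPK (adjusted p = 0.0464) and NUCB2 (0.044) stayed past the threshold with that scaling, and RPS13 (0.0646) and MAPK9 (0.0878) did not. The count of 108 became 12 without U4atac MO 1, 24 without Control MO 3 or U12 MO 2, 27, 51 and 58 without Control MO 1, 2 or 4, 49, 57 and 54 without U6atac MO 1, 2 or 3, 60 without U2 MO 3 and 329 without U2 MO 1. It was 4 (1 higher, 3 lower) with only the groups compared and 27 (9 and 18) in limma without trend and robust settings. It was 71 with no filter, 66 with sample quality weights, 58 (34 and 24) over protein-coding genes and 19 (10 and 9) without U2 MO 1, U4atac MO 1 and U4atac MO 3.

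The comparison of U6atac MO with the control asked the same of the snRNA that takes part in the catalytic core of the minor spliceosome. Ribosomal protein genes had a median log2 fold change of 0.54 with 77 of 83 members above 0 and 10 past the threshold adjusted over the list alone. RPS2 was at 14532 ± 1348 TPM (SD, n = 3) against 10699 ± 2105 TPM (SD, n = 6), not past the threshold over all genes. Mitochondrially encoded genes had a median of 1.18 with 15 of 15 above 0 and 11 past the threshold adjusted over the list alone. Nuclear oxidative phosphorylation genes had a median of 0.51 with 32 of 36 above 0 and 0 adjusted over the list alone. Minor spliceosome proteins had a median of 0.28 with 13 of 15 above 0 and 2 adjusted over the list alone. SCNM1, a component of the minor spliceosome, was at 98.4 ± 3.04 against 54.7 ± 16.1 TPM (log2 fold change 0.89 ± 0.24, limma adjusted p = 0.239).

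limma called 0 genes for U6atac MO against all controls, with 1999 at an unadjusted p under 0.05 (1724 higher, 275 lower) and a median over all genes of 0.17. With sample quality weights 504 genes passed (460 higher, 44 lower). The count was 47 (42 higher, 5 lower) without U2 MO 1, U4atac MO 1 and U4atac MO 3 and 10 with no filter. It was 4 with only the groups compared or without Control MO 4, and 3 with either scaling or over protein-coding genes. camera placed the mitochondrial (adjusted p = 1.14e-08), ribosomal protein (5.61e-09), nuclear oxidative phosphorylation (2.78e-06), Sm, U1 and U5 (median 0.40, 0.00311), snoRNA host (0.33, 0.0311) and minor spliceosome lists (0.0499) higher than other genes. Non-coding RNA (median -0.39, 0.00119), hnRNP (-0.10, 0.016) and histone genes (-0.10, 0.00132) were placed lower. With an estimated correlation the adjusted p was 0.359 or more for every list. U12-type genes had a median of 0.06, which lay below that of all genes (camera adjusted p = 0.177). Against controls 1 to 3, with 985 genes called (851 higher, 134 lower), the medians were 0.81 for ribosomal protein, 1.76 for mitochondrial, 0.83 for nuclear oxidative phosphorylation, 0.53 for minor spliceosome, 0.21 for U12-type and 0.65 for histone genes. Against controls 4 to 6, with 1 gene called (HIST1H3F, lower), they were 0.29, 0.67, 0.22, 0.14, -0.07 and -0.80. With median-of-ratios scaling the median of all genes was 0.06, that of ribosomal protein genes 0.39, and that of U12-type genes turned to -0.06, as it did with quantile normalization (-0.12) and over protein-coding genes (-0.12). The calls of the mitochondrial, ribosomal protein and nuclear oxidative phosphorylation lists held in all 32 alternatives. That of the minor spliceosome list ended in 22, including both control sets, median-of-ratios scaling and the omission of Control MO 1, 2, 3 or 5, U12 MO 2 or 3, U4atac MO 1 or 2, U6atac MO 1 or 3 or any U2 MO library. That of the snoRNA host list ended in 10 of 31, including controls 4 to 6 (median 0.09), median-of-ratios scaling (0.18) and the omission of Control MO 1 or 2, U6atac MO 1 (0.17), U6atac MO 2 or U2 MO 1. Against controls 4 to 6 those of the Sm, U1 and U5 (0.19), non-coding RNA (-0.29) and hnRNP lists (-0.03) ended as well. The hnRNP call also ended without U6atac MO 1, with a median of -0.02 without Control MO 3. The histone call ended without Control MO 5 or 6 or U6atac MO 2, where the median turned to 0.08, 0.08 and 0.08, and without U6atac MO 3 (-0.00063). That median was also 0.04 without Control MO 4, -0.36 without U6atac MO 1, and -0.18, -0.23 and -0.25 without Control MO 1, 2 or 3.

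The comparison of U2 MO with the control asked which transcripts depend on the snRNA of the major spliceosome. Ribosomal protein genes had a median log2 fold change of 0.64, with 79 of 83 above 0 and 47 past the threshold adjusted over the list alone, although 0 passed over all genes. RPS2 was at 11626 ± 1761 TPM (SD, n = 3) against 10699 ± 2105 TPM (SD, n = 6). Nuclear oxidative phosphorylation genes had a median of 0.59 (33 of 36 above 0, 15 adjusted over the list alone) and snoRNA host genes 0.53 (17 of 20 above 0, 7 adjusted over the list alone). GAS5, a snoRNA host, was at 772 ± 51.3 against 570 ± 200 TPM. Immediate early genes had a median of -0.45 (30 of 35 below 0, 0 adjusted over the list alone), and JUN, a subunit of AP-1, was at 127 ± 10.4 against 288 ± 178 TPM.

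limma called 2 genes with U2 MO, and 3255 had an unadjusted p under 0.05 (1344 higher, 1911 lower). RP11-667K14.4 rose from 0.803 ± 1.97 TPM to 13.5 ± 6.28 TPM (log2 fold change 3.32 ± 0.46, adjusted p = 0.0137), where Control MO 2 alone of the controls is listed above 0. RN7SL428P fell from 6.98 ± 2.74 to 0.244 ± 0.422 TPM (log2 fold change -2.63 ± 0.39, adjusted p = 0.0165). camera placed the ribosomal protein (adjusted p = 7.48e-25), nuclear oxidative phosphorylation (9.13e-12), snoRNA host (6.96e-06), mitochondrial (median 0.64, 1.21e-04), histone (0.40, 1.21e-04) and Sm, U1 and U5 lists (0.26, 0.00304) higher and the immediate early list (0.00236) lower. With an estimated correlation the adjusted p was 0.62 or more for every list, and the unadjusted p for ribosomal protein genes was 0.043. U12-type genes had a median of 0.04 (camera adjusted p = 0.183), which turned to -0.12 over protein-coding genes and to -0.09 against controls 4 to 6. Against controls 1 to 3, with 1806 genes called (1072 higher, 734 lower), the medians were 0.90 for ribosomal protein, 0.86 for nuclear oxidative phosphorylation, 0.70 for snoRNA host, -0.74 for immediate early, 1.26 for mitochondrial and 1.02 for histone genes. Against controls 4 to 6, with 1 gene called (RP11-667K14.4), they were 0.40, 0.26, 0.17, -0.28, 0.11 and -0.29, and the immediate early, mitochondrial and histone calls ended. The calls of the ribosomal protein, nuclear oxidative phosphorylation and snoRNA host lists held in every alternative, although the snoRNA host median was 0.24 without U2 MO 1. That of the Sm, U1 and U5 list ended with quantile normalization and without U2 MO 2 (0.16) or U2 MO 3, and the histone median was 0.26 without Control MO 2 or 3. The count of 2 became 245 without Control MO 4 (173 higher, 72 lower), 4 without Control MO 5, 1 without Control MO 1 or 2 and 0 without Control MO 6 or U2 MO 1, and over protein-coding genes alone 97 rose and 711 fell. It was 826 (403 higher, 423 lower) with sample quality weights. It was 6 with median-of-ratios scaling, 3 with quantile normalization or without trend and robust settings, 1 with a pseudocount of 5, and 0 with no filter, with the minimum of 5 TPM or without U2 MO 1, U4atac MO 1 and U4atac MO 3.

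**Figure D2:**
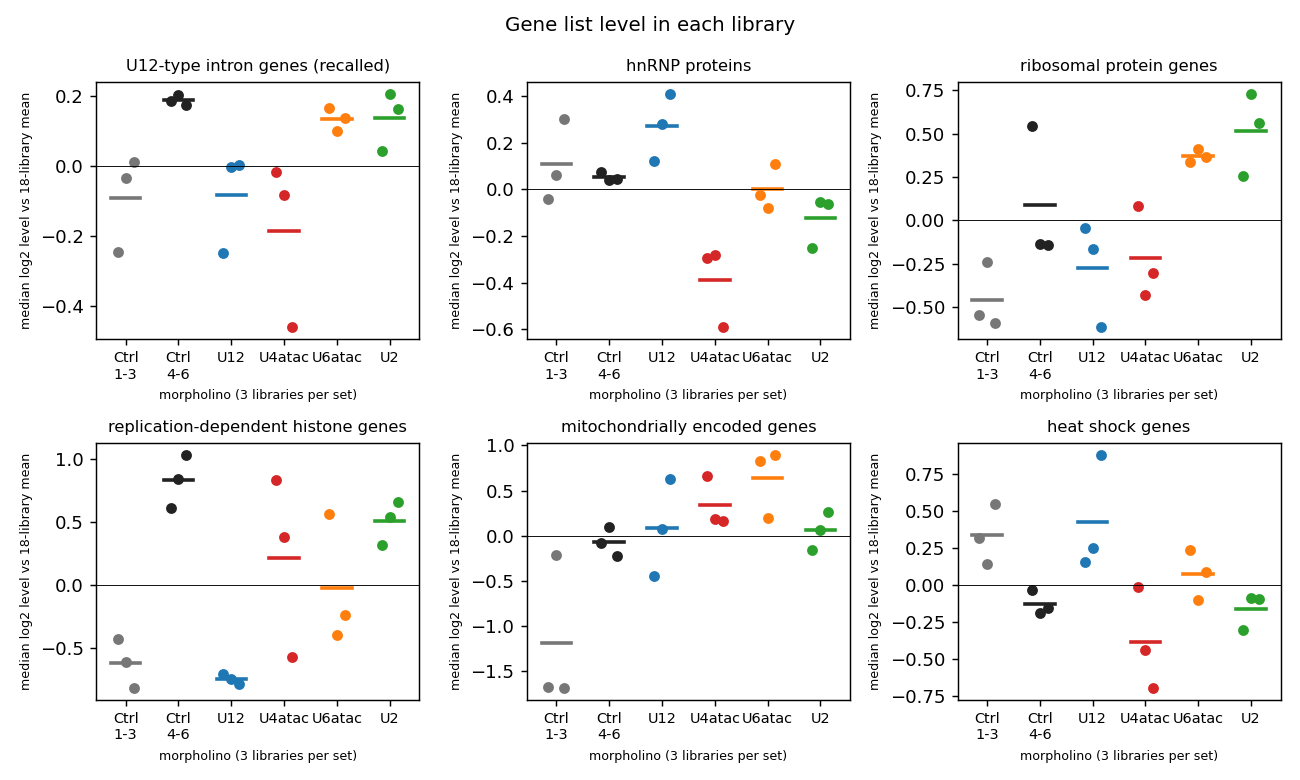
Median over the members of 6 gene lists of log2(TPM + 1) relative to each gene's mean over the 18 libraries (vertical axes), as a point per library, by set of 3 libraries, with a line at the mean of each set. Ribosomal protein genes average 0.52 in U2 MO and -0.22 in U4atac MO, and histone genes -0.62 in controls 1 to 3 and 0.83 in controls 4 to 6.

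U2 MO was compared with the mean of the 3 minor-spliceosome morpholinos, which asks how the spliceosomes differ. Ribosomal protein genes were higher in U2 MO by a median log2 difference of 0.59, with 75 of 83 above 0, 5 called over all genes and 45 adjusted over the list alone. The difference lay mainly against U12 and U4atac MO, with medians of 0.74 and 0.79, and was 0.19 against U6atac MO alone, whose libraries (list medians relative to the mean of 18 libraries of 0.34 to 0.41) lay within the range of U2 MO (0.26 to 0.73). RPL22L1 (chromosome 3 from 170864875 to 170870483) was at 117 ± 24.9 TPM in U2 MO against 39.2, 30.7 and 48.8 TPM in U12, U4atac and U6atac MO (log2 difference 1.57 ± 0.33, limma adjusted p = 0.042). RPS27A, a ubiquitin fusion, was at 1419 ± 175 TPM against 615, 541 and 976 TPM (1.04 ± 0.18, adjusted p = 0.0212), and RPL9, RPL21 and RPS3A were the other members called. In the splicing lists, SF3B6 of the U2 snRNP was higher, at 336 ± 35.2 TPM against 170, 106 and 207 TPM (1.13 ± 0.24, adjusted p = 0.042), as was SNRPG (1.06 ± 0.19, adjusted p = 0.0269). The U2-associated protein CHERP was lower, at 31.2 ± 2.30 TPM against 80.8, 47.8 and 55.2 TPM (-0.90 ± 0.20, adjusted p = 0.0457).

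In all, 34 genes were higher and 69 lower in U2 MO than in the minor-spliceosome morpholinos, and 3582 had an unadjusted p under 0.05. The largest rises included RP11-667K14.4 (3.74 ± 0.43), C2orf74 (1.57 ± 0.35), the prefoldin subunit VBP1 (1.55 ± 0.34) and the dynactin subunit ACTR10 (7.61 TPM in controls and 19.1 TPM in U2 MO, adjusted p = 0.0212). RNY1, a Y RNA at 209, 38.2 and 268 TPM in U12, U4atac and U6atac MO, is listed at 0 in U2 MO. AC008993.2 (-3.51 ± 0.49), HLA-DPA1 (-2.36 ± 0.47), RP11-378J18.9 (-2.34 ± 0.41) and PALM3 (-2.17 ± 0.37) were the other largest falls. COX7A2 (0.88 ± 0.18), 1 of 36 nuclear oxidative phosphorylation genes called and 5 adjusted over the list alone (list median 0.46), and the snoRNA host SNHG8 (1.39 ± 0.31; list median 0.43, 8 of 20 adjusted over the list alone) were higher. ZFP36, which promotes decay of AU-rich mRNAs, was lower (-1.49 ± 0.32), with 12 of 35 immediate early genes lower and 1 higher adjusted over the list alone (median -0.79). TP53I3, a p53 target, was lower too (-1.15 ± 0.25, list median -0.44, 8 of 26). It was at 4.65 TPM in U2 MO, 7.06, 15.1 and 13.9 TPM in U12, U4atac and U6atac MO and 7.82 TPM in controls. HERPUD1, of the unfolded protein response, was also lower (-1.03 ± 0.23, list median -0.33, 7 of 27). It was at 288, 145 and 200 TPM in U12, U4atac and U6atac MO. U2 MO lay within the SD of controls (121 ± 32.0 TPM). The immediate early, p53 and stress response lists were also higher in controls 1 to 3 than 4 to 6 (medians 0.58, 0.12 and 0.35). U12 MO libraries lay closer to controls 1 to 3, and their part in these falls was not tested.

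camera placed the ribosomal protein (adjusted p = 2.68e-25), nuclear oxidative phosphorylation (2.21e-12), histone (median 0.72, 1.21e-11), snoRNA host (5.54e-06), U12-type (0.16, 9.54e-05), DNA replication (0.08, 8.68e-04) and Sm, U1 and U5 lists (0.15, 0.00452) higher in U2 MO. It placed the immediate early (2.88e-06), p53 (0.0266) and stress response lists (0.0483) lower. With an estimated correlation the adjusted p was 0.488 or more for every list, and the unadjusted p for ribosomal protein genes was 0.0414. The median of all genes was -0.15, and 67 genes rose and 60 fell with quantile normalization, 119 and 1146 over protein-coding genes, where DNA replication genes turned to -0.05. The stress response call ended in 12 of 32 alternatives, including median-of-ratios scaling and the omission of U2 MO 1, 2 or 3, U4atac MO 1 (median -0.22), U12 MO 2, U6atac MO 2 or Control MO 4. The p53 call ended without U2 MO 1 (-0.26) or U2 MO 3 (-0.55). That of the Sm, U1 and U5 list ended with quantile normalization and without U2 MO 2 (0.10) or U2 MO 3 (0.17), with a median of 0.09 without U4atac MO 3, where that of U12-type genes was 0.10. The DNA replication call ended with quantile normalization, with medians of 0.23, 0.03, 0.14 and 0.06 without U2 MO 1, U2 MO 2, U4atac MO 1 or U6atac MO 1. The calls of the other lists held in every alternative. The count of 103 became 3 without U6atac MO 1 or without U2 MO 1, 15, 19, 20 and 19 without U12 MO 2, U12 MO 3, U2 MO 3 or U6atac MO 3, 26, 32 and 34 without U6atac MO 2, U12 MO 1 or Control MO 5, 46, 50, 58 and 58 without Control MO 2, U4atac MO 2, U4atac MO 1 or Control MO 1, and 254 and 405 without U4atac MO 3 or U2 MO 2. It was 2190 (672 higher, 1518 lower) with sample quality weights and 225 (112 and 113) with only the groups compared. It was 178 (70 and 108) with median-of-ratios scaling and 496 and 508 with controls 1 to 3 or 4 to 6. It was 61 without trend and robust settings, 48 (24 and 24) with a pseudocount of 5, 27 with no filter and 6 without U2 MO 1, U4atac MO 1 and U4atac MO 3.

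U12 MO was also compared with U4atac MO. HNRNPK was at 406 TPM in U12 MO and 200 TPM in U4atac MO (log2 difference 1.01 ± 0.19, limma adjusted p = 0.0191), and HNRNPA2B1 at 1106 and 408 TPM (1.42 ± 0.33, adjusted p = 0.0308), with 5 of 26 hnRNP genes called and 11 adjusted over the list alone. HSPD1, the mitochondrial chaperonin HSP60, was at 972 ± 354 and 350 ± 19.0 TPM (SD, n = 3, log2 difference 1.41 ± 0.28, limma adjusted p = 0.0198). HSPH1 was at 197 ± 162 and 25.8 ± 6.18 TPM (2.61 ± 0.62, adjusted p = 0.0371). Of 21 heat shock genes, 4 were called and 8 passed adjusted over the list alone. Relative to the mean of 18 libraries, the heat shock median was 0.15 and 0.25 in U12 MO 1 and 2 and 0.88 in U12 MO 3. U12 MO libraries were closer to controls 1 to 3 and U4atac MO libraries to controls 4 to 6. This comparison cannot separate those sets from the morpholinos. The U2 snRNP gene SF3A1 was at 342 and 115 TPM (1.56 ± 0.35, adjusted p = 0.027). In cholesterol synthesis, 6 of 21 genes were called and 8 adjusted over the list alone, among them CYP51A1 at 45.9 and 21.5 TPM (1.05 ± 0.23, adjusted p = 0.0247) and SREBF2, its transcriptional regulator, at 16.3 and 6.34 TPM (1.23 ± 0.27, adjusted p = 0.0256).

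Altogether 418 genes were higher and 27 lower in U12 than in U4atac MO, with 3132 at an unadjusted p under 0.05. By camera, hnRNP (median 0.55, adjusted p = 6.89e-08), heat shock (0.80, 4.28e-05), stress response (0.47, 0.00442; 10 adjusted over the list alone), cholesterol (0.45, 0.0083), mitosis (0.39, 0.0083) and SR genes (0.34, 0.0429) were higher, and histone (-1.05, 1.62e-15) and nuclear oxidative phosphorylation genes (-0.25, 0.0125) lower. With an estimated correlation the adjusted p was 0.268 or more for every list (unadjusted p for hnRNP genes 0.0128), and in fry hnRNP genes had an adjusted p of 0.002. The hnRNP, heat shock and histone calls held in all 32 alternatives, and those of the stress response and cholesterol lists in all but the minimum of 5 TPM, with medians of 0.54 for heat shock and 0.29 for cholesterol genes without U4atac MO 3. The SR call ended in 16, among them either scaling, controls 1 to 3 and the omission of U12 MO 3 (0.12), U4atac MO 3 (0.19), Control MO 6, U2 MO 1 or U2 MO 3, and its median was 0.57 without U12 MO 1. The mitosis call ended with either scaling, over protein-coding genes and with the minimum of 5 TPM, and its median was 0.21 without U12 MO 3 or U4atac MO 2. The nuclear oxidative phosphorylation call ended with sample quality weights, without 3 libraries together, and without U12 MO 3 (-0.08) or U4atac MO 3 (-0.36), with medians of -0.38, -0.08 and -0.37 without U12 MO 1, U4atac MO 1 or U4atac MO 2. With median-of-ratios scaling 5 genes were higher and 8 lower, as the median of all genes moved from 0.08 to -0.10; the splits were 77 and 32 with quantile normalization and 8 and 7 over protein-coding genes. The count was 0 without U12 MO 2 or U12 MO 3, 105 and 101 without U4atac MO 1 or U4atac MO 3, 695 and 859 without Control MO 3 or U2 MO 1, 156 with only the groups compared and 2464 (1872 higher, 592 lower) with sample quality weights. It was 701 and 799 with controls 1 to 3 or 4 to 6, 690 with the minimum of 5 TPM, 239 with no filter, 136 without trend and robust settings and 22 (14 higher, 8 lower) without U2 MO 1, U4atac MO 1 and U4atac MO 3.

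U12 and U6atac MO differed in 0 genes by limma, with 2332 at an unadjusted p under 0.05 (898 higher, 1434 lower in U12 MO). The count was 1509 with only the groups compared and 4483 with sample quality weights. It was 333 and 409 with controls 1 to 3 or 4 to 6, 14 without Control MO 4 and 5 with no filter. Nuclear oxidative phosphorylation genes had a median log2 difference of -0.75 (32 of 36 below 0, 24 lower and 1 higher adjusted over the list alone) and ribosomal protein genes -0.65 (76 of 83 below 0, 27 adjusted over the list alone). Histone genes had a median of -0.74 (0 adjusted over the list alone), snoRNA host genes -0.40 (6) and hnRNP genes 0.29 (1). These camera calls (adjusted p of 2.11e-11, 2.38e-12, 3.59e-05, 7.93e-04 and 5.82e-05) were lost with an estimated correlation, where the unadjusted p was 0.0735, 0.14, 0.385, 0.196 and 0.0478 and no list passed after adjustment. They held in every alternative, with medians of -0.43 for histone and -0.26 for snoRNA host genes without U6atac MO 1. U4atac and U6atac MO also differed in 0 genes by limma, with 1496 at an unadjusted p under 0.05 (147 higher, 1349 lower in U4atac MO) and a median of all genes of -0.22. The count was 15 without U2 MO 1, U4atac MO 1 and U4atac MO 3, 6 without U4atac MO 2 and 3 without U2 MO 1. It was 7 with no filter or sample quality weights, 6 with a pseudocount of 5, 2 with controls 1 to 3 and 1 with only the groups compared. Ribosomal protein genes had a median of -0.61 (82 of 83 below 0, 2 adjusted over the list alone), nuclear oxidative phosphorylation genes -0.50 (36 of 36, 1), Sm, U1 and U5 genes -0.42 (34 of 34, 2) and mitosis genes -0.36 (30 of 30, 0). Their camera adjusted p values were 1.46e-14, 3.4e-07, 5.95e-07 and 0.00385, and 0.421 or more with an estimated correlation. With median-of-ratios scaling the median of all genes moved from -0.22 to 0.03, and the mitosis call ended (median -0.06), as it did with quantile normalization (-0.11) and over protein-coding genes (0.01), while the calls of the other 3 lists held in all 32 alternatives.

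**Figure D3:**
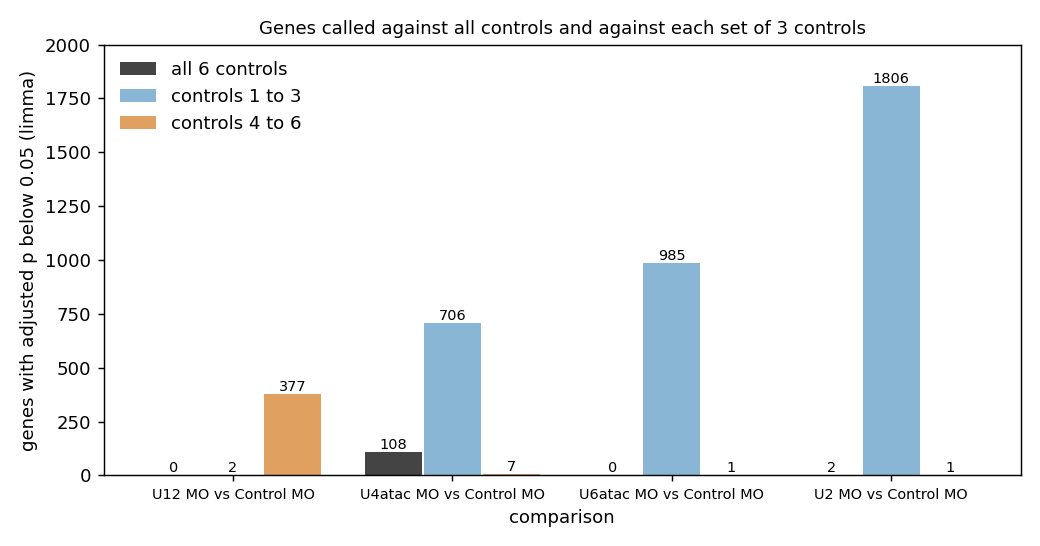
Number of genes past a limma adjusted p of 0.05 (vertical axis) for each morpholino, with a bar each for all 6 controls, controls 1 to 3 and controls 4 to 6. U12 MO has 0, 2 and 377 calls, and U2 MO 2, 1806 and 1.

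Fold changes of U4atac and U6atac MO were correlated across the 17460 genes, which are not independent replicates, with Pearson's r of 0.57 and Spearman's rho of 0.58, against 0.33 and 0.31 for simulated unchanged groups that share the 6 controls. Their covariance was 0.135 against a simulated 0.0523. The simulation drew independent values and left out the 2 sets of controls. U4atac, U6atac and U2 MO libraries lay closer to controls 4 to 6 and U12 MO libraries to controls 1 to 3. That can raise r among the former and lower it for U12 MO without an effect of the morpholinos, so the simulated values are no full reference here. With controls 1 to 3 for U4atac MO and 4 to 6 for U6atac MO, r was 0.18, and 0.09 with the sets exchanged. For U6atac and U2 MO, r was 0.45 (rho 0.41, covariance 0.119) with shared controls and 0.15 and 0.0023 with the sets, and for U4atac and U2 MO 0.32 (rho 0.28, covariance 0.0983), 0.12 and -0.08. U12 MO had an r of 0.07 with U4atac MO (rho 0.02, covariance 0.0137), 0.06 with U6atac MO (rho 0.03, covariance 0.0108) and -0.06 with U2 MO (rho -0.11, covariance -0.0127), and with the sets exchanged -0.43, -0.50 and -0.52. Of the called genes, RN7SL428P alone was shared between any 2 of the 4 comparisons. It fell with U4atac and U2 MO, where 0.00498 genes are expected of independent lists. That value leaves out the control libraries shared by both comparisons. With 0 genes called for U12 and for U6atac MO, every pair with either had to share 0. U2 MO had 2 called genes, so these overlaps do not measure how far the responses are shared.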

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

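Of the tests given here, those of handling in sets, of both explanations for the falls with U4atac MO, of ribosomal protein genes against each morpholino alone and of leaving out U2 MO 1 were chosen after the result was seen. Among the 6 controls, 50 items were examined for a library far from the others. They were named genes and library measures such as the share of short non-coding RNAs. Of these, 5 stood apart, all of them genes, where chance marks about 1 in 20 groups. Control MO 2 was alone above 0 for XX-FW80269A6.1 (0.205 TPM, gap over range 1) and for RP11-667K14.4 (4.82 TPM, gap over range 1). Control MO 1 was low for RP5-1120P11.1 (0.0827 TPM against 0.259 to 0.336 TPM, gap over range 0.696). Control MO 5 was high for EVA1A (4.16 TPM against 0 to 1.48 TPM, gap over range 0.644) and Control MO 3 for CYP51A1 (59.9 TPM against 35.0 to 40.1 TPM, gap over range 0.793). By limma tests of the difference itself, libraries differed in 103 genes between U2 MO and the minor-spliceosome morpholinos and in 445 genes between U12 MO and U4atac MO, which does not separate the morpholino from the set in which a library lay.

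For U4atac MO, 3 of the 84 splits of the 9 libraries, the real one among them, gave at least the real 108 genes. The others were controls 1 to 3 against the rest, with 1084 genes, and Control MO 1, Control MO 3 and U4atac MO 3 against the rest, with 675. The former calls many times the real count, which points to a structure of the samples. Splits take the libraries as exchangeable, which controls in 2 sets are not, so this share does not exclude chance. For U2 MO, 5 of 84 splits gave at least the real 2 genes (highest other 2077, again controls 1 to 3), so chance is not excluded. For U12 MO and U6atac MO, with 0 genes called by limma and 995 and 1999 at an unadjusted p under 0.05, all 84 of 84 splits gave as many, as any split must against 0 genes, so the splits decide nothing (highest other 1098 and 1754). For U2 MO against the minor-spliceosome morpholinos, 1 of 100 splits, the real one itself, gave as many as 103 (highest other 55). The random splits also mixed libraries of groups that differ from each other, such as U12 and U4atac MO, which widens the spread within groups. This share therefore does not exclude chance either. The 10 splits of 6 libraries are too few for a share under 0.05: the real and highest other counts were 445 and 1 for U12 against U4atac MO (1 split as large), 0 and 1 for U12 against U6atac MO (10 splits), 0 and 3 for U4atac against U6atac MO (10 splits) and 733 and 2 for the control sets (1 split).

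Controls 1 to 3 and 4 to 6 differed in 733 genes. The share of short non-coding RNAs as the whole cause is argued against by the 906 genes that differed with median-of-ratios scaling, and transcript length and GC content by the 1190 genes after correction (815 before it, over 14337 genes). Genes higher and lower in controls 1 to 3 numbered 411 and 495 with that scaling and 663 and 527 after that correction, against 177 and 556 without either. The excess of lower genes thus shrank or turned, and a count can rise as the spread falls. For both, a part in the difference stays open. Handling of the libraries in sets that cross the groups stays open, since the labels give no batch. Across genes, which are not independent replicates, the difference had an r of 0.607 with that between U12 MO and the mean of the other morpholinos, but this restates the resemblance of U12 MO to controls 1 to 3 from which the test was chosen. No biological explanation was tested.

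Falls made up 80.6% of the genes called with U4atac MO. They made up 40.6% with median-of-ratios scaling, which moves all genes of a library alike and so names no cause. A larger share of short non-coding RNAs was not seen beyond the spread: U4atac MO averaged 1.77 percentage points above the controls (SD 8.62, n = 3, and 6.58, n = 6), which leaves it open. U4atac MO 3 may account for the excess, since falls made up 26.9% without it. That library also had the highest share of short non-coding RNAs of all 18 (44.1%) and the lowest of protein-coding genes (45.4%), so these 2 explanations are not separate. Rescaled over protein-coding genes, 34 genes rose and 24 fell, which as a scaling likewise names no cause. A dependence of these transcripts on U4atac snRNA stays open, as untested.

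Ribosomal protein genes were higher in U2 MO than in the minor-spliceosome morpholinos by a median log2 difference of 0.59. Transcript length and GC content as the whole cause are argued against by a median of 0.67 after correction, the resemblance of U12 MO to controls 1 to 3 by 0.51 against the mean of U4atac and U6atac MO, and U2 MO 1, the library with the fewest genes above 0, by 0.73 without it. That 0.51 combines 0.79 against U4atac MO with 0.19 against U6atac MO, whose libraries lay within the range of U2 MO, and the difference from U6atac MO alone was not tested. Reads shared with ribosomal protein pseudogenes and an effect of the blocked snRNAs were not tested and stay open.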

How the results depend on the processing

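Sample quality weights, rescaling over protein-coding genes, the omission of 3 libraries together and the odd and even split of the controls were chosen after seeing the data. TPM keeps no record of depth, so what depth limits could not be examined. Alternatives that need counts (DESeq2) or a genome (other definitions of U12-type introns) were not run. Of values of named genes under alternatives, 5942 kept their side of the threshold, with any turn of sign smaller than the standard error, 81 passed it anew, 537 no longer passed, 70 moved, and the sign turned in 0 for genes past the threshold and 233 for others. Of list medians, apart from those of U12-type genes against the control, 4714 kept it in the same sense, 131 passed it anew, 194 no longer passed, 145 moved, and 40 past the threshold changed sign or came to 0. Over all lists the sign turned in 255, of which 217 were of lists not past the threshold. Unless stated, the cause was not tested.

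Counts are given below for U12, U4atac, U6atac and U2 MO against the control, U2 MO against the minor-spliceosome morpholinos, U12 against U4atac MO, U12 against U6atac MO and U4atac against U6atac MO, in that order, where the counts reported above were 0, 108, 0, 2, 103, 445, 0 and 0. They were 0, 96, 0, 1, 48, 447, 0 and 6 with a pseudocount of 5 and 0, 100, 0, 2, 121, 440, 0 and 0 with 0.1. They were 3, 71, 10, 0, 27, 239, 5 and 7 with no filter and 0, 132, 0, 0, 127, 690, 0 and 0 with a minimum of 5 TPM. They were 0, 69, 3, 6, 178, 13, 0 and 0 with median-of-ratios scaling, 0, 85, 3, 3, 127, 109, 0 and 0 with quantile normalization and 0, 58, 3, 808, 1265, 15, 0 and 0 over protein-coding genes. They were 0, 27, 0, 3, 61, 136, 0 and 0 in limma without trend and robust settings and 0, 4, 4, 2, 225, 156, 1509 and 1 with only the groups compared, where fewer libraries estimate the spread. They were 2, 706, 985, 1806, 496, 701, 333 and 2 with controls 1 to 3 and 377, 7, 1, 1, 508, 799, 409 and 0 with controls 4 to 6. They were 942, 66, 504, 826, 2190, 2464, 4483 and 7 with sample quality weights and 1, 19, 47, 0, 6, 22, 1, 15 without U2 MO 1, U4atac MO 1 and U4atac MO 3. Leaving out each library in turn, they ranged from 0 to 0, from 12 (without U4atac MO 1) to 329 (without U2 MO 1), from 0 to 4 (without Control MO 4), from 0 (without Control MO 6 or U2 MO 1) to 245 (without Control MO 4), from 3 (without U6atac MO 1 or U2 MO 1) to 405 (without U2 MO 2), from 0 (without U12 MO 2 or U12 MO 3) to 859 (without U2 MO 1), from 0 to 14 (without Control MO 4) and from 0 to 6 (without U4atac MO 2).

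The replicate numbers did not pair the libraries: over 30 pairs with the same number, deviations from group means had correlations from -0.11 to 0.31 (median 0.0036), 2 of them above 0.1, against a median of -0.0096 over 60 other pairs. With the replicate block, where controls 4 to 6 have no partner, the counts in the same order were 2, 662, 971, 1780, 378, 682, 289 and 3.

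With controls 1 to 3, and with the replicate block alike, the median for U12 MO turned to 0.037 for U12-type (all genes 0.15; camera adjusted p for a place below other genes 0.048, and 0.0651 with the block), 0.098 for snoRNA host, 0.11 for nuclear oxidative phosphorylation and 0.16 for ribosomal protein genes; for U4atac MO it turned to 0.012 for U2 snRNP genes and was -0.029 for U12-type genes, no longer past the threshold (adjusted p = 0.229 and 0.233). Histone genes with U6atac MO turned to 0.65 with controls 1 to 3 and 0.61 with the block, and with controls 4 to 6 turned to -0.58 with U4atac MO and -0.29 with U2 MO. U12-type genes with U6atac MO moved to -0.056 (median-of-ratios), -0.12 (quantile, and protein-coding genes) and -0.071 (controls 4 to 6), and with U2 MO to -0.087 (controls 4 to 6) and -0.12 (protein-coding genes). U12-type genes with U4atac MO were at -0.15 without the 3 libraries (adjusted p = 0.0964). For U4atac against U6atac MO, U2 snRNP, SR and DNA replication genes turned to 0.021, 0.0087 and 0.0067 with median-of-ratios scaling, and U2 snRNP genes to 0.037 with quantile normalization. Over protein-coding genes, U12-type, U2 snRNP, SR, hnRNP, DNA replication and mitosis genes turned to 0.047, 0.092, 0.080, 0.020, 0.076 and 0.012. Immediate early genes turned to -0.0090 without the 3 libraries and ranged from -0.30 (without U4atac MO 1), with -0.16 without U6atac MO 2, to 0.30 (without U4atac MO 3). Histone genes ranged from -0.050 (without U4atac MO 1) to 0.66 (without U4atac MO 3), and non-coding RNA genes came to 0 without U4atac MO 3 or U6atac MO 2, with sample quality weights and without the 3 libraries. DNA replication genes in U2 MO against the minor-spliceosome morpholinos turned to -0.052 over protein-coding genes. Leaving out libraries in turn, U12-type medians ranged from -0.18 to -0.030 (without U12 MO 1) with U12 MO, -0.34 to -0.058 (without U4atac MO 3) with U4atac MO, 0.010 to 0.10 with U6atac MO and -0.061 (without Control MO 1) to 0.15 with U2 MO. Histone genes with U4atac MO ranged from -0.11 (without U4atac MO 1) to 0.59 (without U4atac MO 3), with -0.0047 without Control MO 3. With U6atac MO they ranged from -0.36 (without U6atac MO 1) to 0.085 (without Control MO 5), with 0.038 and 0.078 without Control MO 4 or 6 and 0.078 without U6atac MO 2. With U12 MO, ribosomal protein genes ranged from -0.20 (without U12 MO 1) to 0.082 (without U12 MO 3), with 0.078 without Control MO 4, and nuclear oxidative phosphorylation genes from -0.38 (without U12 MO 1) to 0.0079 (without U12 MO 3).

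Correlations of fold changes with controls 1 to 3 and 4 to 6 split, exchanged, split by odd and even number, and exchanged, were 0.028, -0.43, -0.0067 and -0.28 for U12 and U4atac MO, 0.091, -0.50, 0.037 and -0.35 for U12 and U6atac MO, 0.083, -0.52, -0.024 and -0.39 for U12 and U2 MO, 0.18, 0.086, 0.34 and 0.23 for U4atac and U6atac MO, 0.12, -0.079, 0.20 and 0.058 for U4atac and U2 MO, and 0.15, 0.0023, 0.24 and 0.18 for U6atac and U2 MO, where split controls share no chance values.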

Other observations

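Among the markers of other cell types, with U4atac MO, haematopoietic markers had a median log2 fold change of 0.60 over 6 genes (camera adjusted p = 0.0565), in which HBA1, a globin, was at 33.3 ± 29.9 TPM (SD, n = 3) against 8.80 ± 2.46 TPM (SD, n = 6) in controls (limma adjusted p = 0.144). The list median was 0.11 without U4atac MO 1. The medians of this list were 0.11, 0.36 and -0.39 with U12, U6atac and U2 MO (camera adjusted p = 0.838, 0.369 and 0.325). Mesenchymal markers (3 genes, no test) had medians of 0.65, 0.11, 0.04 and 0.01 with U12, U4atac, U6atac and U2 MO, and keratin markers (3 genes, no test) 0.13, 0.27, 0.23 and -0.13. Interferon response genes had a median of 0.33 with U4atac MO (camera adjusted p = 0.0565), with 1 gene higher and 1 lower adjusted over the list alone, and ranged from 0.11 without U4atac MO 1 to 0.67 without U4atac MO 3. p53 targets had medians of 0.12, 0.08, 0.11 and -0.31 with U12, U4atac, U6atac and U2 MO, of which that with U6atac MO turned to -0.07 with quantile normalization and -0.09 over protein-coding genes, and that with U4atac MO to -0.02 against controls 1 to 3 and -0.11 without U4atac MO 1. Without U2 MO 1 the median with U2 MO was -0.17.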
